A study of Mus musculus with 9 samples.

How the data were processed

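Poly-A RNA was sequenced from 9 libraries of J774A.1, a mouse macrophage cell line, with 3 libraries in each of 3 groups. Control cells were cultured normally, M2 cells received IL-4 and IL-13 (10 ng/mL), and Q11 cells received Q11 together with both cytokines, per the labels. Q11 is named in the series title as an inhibitor of the cytochrome P450 enzyme CYP2E1, and its dose was not given in the sources used here. The cytokine dose was given for the M2 libraries only, and the duration of treatment was not given. Libraries were made with a NEBNext Ultra kit, per the labels' protocols. HISAT2 2.0.5, StringTie 1.3.3b and the mouse build GRCm38 are named per the submitters' processing notes, while the annotation release and the counting settings were not given in the sources used here. The authors deposited 1 table of TPM for 26157 genes, scaled so that every column sums to the same total. Gene IDs were matched to GENCODE M21, which held 25573 of them (97.8%). The other 584 IDs kept the symbol of the table, or the ID itself.

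TPM keep no depth, but TPM multiplied by the exon length of each gene came in whole multiples of 1 step per library. With a tolerance of 0.1 read, 98.9% to 99.2% of the low values (up to 20 reads) were whole, and 15809436 to 17089172 reads were recovered in 8 libraries and 32180960 in Q11 replicate 2. A gene with 0 reads in a library could still stand for up to 3 reads at that depth, and such limits cover counting error only. Q11 replicate 2 held fewer recovered reads than Q11 replicate 3 in only 10 of 19235 genes. The fit decided on before the data were examined was kept, and its values are given beside those of a fit in which the reads of Q11 replicate 3 were subtracted from Q11 replicate 2 and the TPM of that column recomputed. That fit, called "shared reads separated" here, was chosen after seeing the data. It left 15330246 reads in Q11 replicate 2, and it tested 13971 genes, because it needs a gene length.

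Genes with at least 1 TPM in at least 3 of the 9 libraries were tested (14207 genes). Values were analysed as log2(TPM + 1), so fold changes on this scale understate the changes of low genes. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), which leaves 6 residual degrees of freedom with a median of 2.85 prior degrees of freedom. The 3 contrasts were M2 against control, Q11 against M2 and Q11 against control. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The labels do not say whether libraries of a group come from separate cultures, so the p-values measure the spread between these samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.

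Of 29 gene lists, 24 had at least 3 genes tested and were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 24 lists. The lists were markers of IL-4 activated (M2) macrophages, the IL-4 and STAT6 pathway, inflammatory (M1) genes, interferon response, PPAR targets and fatty acid use, cholesterol synthesis, LXR targets and sterol efflux, CYP, AhR and xenobiotic genes, NRF2 antioxidant genes, ATF4 amino acid stress, ER unfolded protein response, heat shock, glycolysis and hypoxia, OXPHOS and TCA cycle, cell cycle, p53 targets, cell death and ferroptosis, MHC class II presentation and costimulation, lysosome and phagocytosis, matrix and angiogenic genes, macrophage identity, ribosomal proteins, mitochondrially encoded genes and housekeeping genes. The other 5 lists held markers of other cell types and had fewer than 3 genes tested. Lists, model, filter, threshold and the rule for named genes were fixed before the data were examined.

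The genes named for each comparison were the 10 largest rises and the 10 largest falls among genes past the threshold with at least 5 TPM in the higher group and no overlap between groups, leaving out clone-like symbols. Up to 4 members past the threshold from each list were added, with 16 genes that were to be given whatever their values (Cyp2e1, Arg1, Mrc1, Retnla, Chil3, Cd163, Il10, Tgfb1, Nos2, Tnf, Il1b, Il6, Cd86, Pparg, Stat6 and Il4ra). Cd163 was not analysed here. The largest changes are summarised where they were small RNA genes.

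Movement of the Q11 libraries towards control was measured as a slope through 0 of the Q11 against M2 fold change on the M2 against control fold change, over genes called in M2 against control. It was cross-fitted over 6 splits of the M2 libraries, because both comparisons share those libraries. The chance effect of shared libraries was taken from 100 simulations of unchanged groups, in which as many genes as were called were also chosen by the smallest p in M2 against control.

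Simulated data were used to test the fit, with a spread between libraries that was set and not estimated from these data. In them 100 genes were changed by 0.5 and 100 by 1 on the log2 scale, all drawn from genes with a mean of at least 5 TPM. In M2 against control the fit recovered 49% and 99% of them with 11 false calls among 13981 genes. In Q11 against M2 it recovered 51% and 100% with 10 false calls among 13980 genes. In Q11 against control it recovered 55% and 99% with 10 false calls among 13980 genes. With no changed genes it made 3, 3 and 0 calls in the same order.

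Alternatives were other pseudocounts, filters, scalings and forms of the limma fit, a replicate block, leaving out each library, limma-voom on recovered reads, camera with an estimated correlation, fry (which tests a list against no change), and separation or averaging of the Q11 libraries that share reads. The kit protocol does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Near-identical family members, such as Mgl2 with Clec10a, Pilra with Pilrb1, the CC chemokines Ccl2, Ccl7 and Ccl12, and ribosomal protein genes with their pseudogenes, could exchange reads and are uncertain to that extent.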

Results

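Transcript levels were measured in 9 libraries of J774A.1 mouse macrophages, 3 from control cells, 3 from cells given IL-4 and IL-13 (M2), and 3 from cells given Q11 together with the same cytokines (Q11). Between 15809436 and 17089172 reads were recovered in 8 libraries. Q11 replicate 2 held 32180960 reads, and in only 10 of the 19235 genes read in Q11 replicate 3 did it hold fewer reads than that library. Against each of the other 7 libraries it held fewer reads in 1928 to 2406 genes. These Q11 libraries were therefore treated as sharing reads and as not independent, and values with the shared reads separated, a fit chosen after seeing the data, are given beside the fit of all libraries as deposited, and counts of list members from it are marked separated. Without the shared reads, 15330246 reads were left in Q11 replicate 2. The first principal component of the libraries as deposited held 18.4% of the variance and set the 3 control libraries apart. The second held 17.0% and set M2 replicate 3 furthest from the rest (29.9). On the second, Q11 replicates 2 and 3 lay at the opposite end (-16.4 and -20.6), apart from Q11 replicate 1 (8.97).

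**Figure D1:**
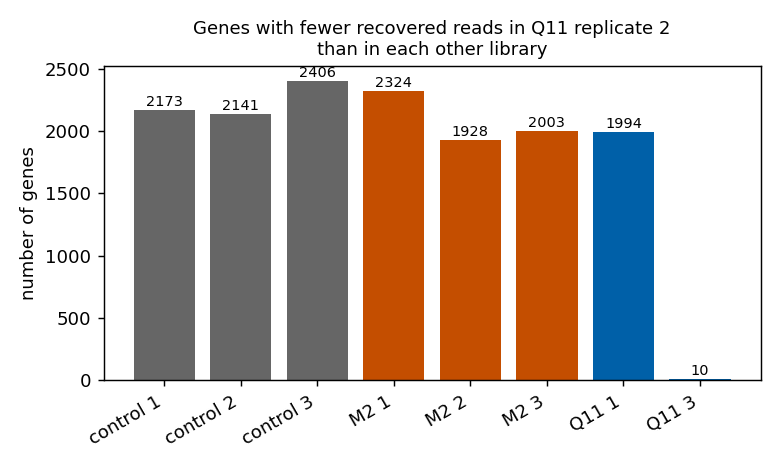
Number of genes with fewer recovered reads in Q11 replicate 2 than in each other library, with 1 bar per library coloured by group. The bar for Q11 replicate 3 stands at 10 genes, and the bars of the 7 other libraries lie between 1928 and 2406.

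Cyp2e1, which encodes the enzyme named as the target of Q11 (ENSMUSG00000025479, GRCm38 chromosome 7, 140763739 to 140774987), was almost unread in these cells. It had 1 read each in control replicate 2, Q11 replicate 2 and Q11 replicate 3, and 0 reads in the other 6 libraries, which allows up to 3 reads in each of them. As these Q11 libraries were treated as sharing reads, the 1 read of replicate 2 may be that of replicate 3. Cyp2e1 was below the filter, so no change in it was detectable at this depth.

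M2 against control asked what IL-4 and IL-13 changed in these cells. Mgl2 and Mrc1, which encode lectins on the list of M2 markers, were among the 10 largest rises. Mgl2, a galactose-type lectin (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550), rose 7.62-fold, from 132 ± 1.93 to 1004 ± 90.002 TPM (SD, n = 3 libraries in each group here and below). Mrc1, the mannose receptor CD206 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), rose 4.45-fold, from 19.6 ± 0.666 to 87.3 ± 1.71 TPM. Toll-like receptor gene Tlr2 (ENSMUSG00000027995, chromosome 3, 83836272 to 83841767) fell from 125 ± 3.54 to 59.5 ± 2.18 TPM, and the lysozyme gene Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) from 6859 ± 244 to 3596 ± 223 TPM.

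Of the 24 measured M2 markers, 12 rose and 4 fell (13 and 4 adjusted over the list alone, 10 and 3 separated), and the median change was 0.54 on the log2 scale (camera adjusted p = 9.84e-05). The call was lost when the correlation between genes was estimated (adjusted p = 0.123 with an estimated correlation). Mgl2 rose by 2.92 (95% interval 2.79 to 3.05, limma adjusted p = 1.40e-08) and Mrc1 by 2.10 (2.01 to 2.19, adjusted p = 1.36e-08). Clec10a, the neighbouring lectin, rose from 75.0 to 223 TPM and Slc7a2, a transporter of cationic amino acids, from 5.73 to 18.8 TPM. Arg1, the arginase of M2 cells, lay at 0.302 ± 0.186 TPM in control and 3.56 ± 2.36 TPM in M2 libraries, on 4, 5 and 1 reads against 32, 17 and 66. Its change of 1.69 (0.81 to 2.57) passed with an adjusted p of 0.0228. The call was lost without control replicate 1 (adjusted p = 0.0592), control replicate 2 (0.0501), control replicate 3 (0.0739), M2 replicate 1 (0.0575) or M2 replicate 3 (0.0557), and with no filter on low values (0.0539). Matrix protease gene Mmp9 fell from 334 to 205 TPM although it is on the same list. Retnla had 1 read in M2 replicate 2 and 0 in the other libraries, and Chil3 had 4, 0 and 4 reads in the M2 libraries and 0 in control, so both were below the filter.

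In the IL-4 and STAT6 pathway, 3 of 19 genes rose and 3 fell (3 and 4 adjusted over the list alone, 2 and 3 separated), and the list as a whole did not pass (camera adjusted p = 0.436; median -0.04, mean 0.04). Socs1, a feedback inhibitor of JAK kinases, rose from 1.53 to 7.10 TPM, Jak2 from 22.1 to 38.3 TPM, and the receptor chain gene Il13ra1 fell from 28.9 to 16.9 TPM. Stat6 was at 155 ± 3.35 TPM in control and 155 ± 5.63 TPM in M2 libraries (adjusted p = 0.926), and Il4ra at 16.0 and 16.7 TPM (adjusted p = 0.623). Among other large changes, Rnf19b, which encodes a ubiquitin ligase, rose from 237 to 742 TPM and Azin2, an antizyme inhibitor, from 8.08 to 34.2 TPM. Pparg (adjusted p = 0.415), Tgfb1 (0.791) and Il10 (0.0968) did not pass, though Il10 passed without control replicate 1 (0.0243).

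Inflammatory (M1) genes went down as a group. Of 33 measured, 21 fell and 3 rose (24 and 3 adjusted over the list alone, 20 and 3 separated), with a median of -0.36 (camera adjusted p = 3.61e-11). Tlr2 fell by 1.06 (adjusted p = 6.69e-07), the cytokine gene Tnf from 141 ± 1.52 to 78.3 ± 7.39 TPM (adjusted p = 3.14e-04), the chemokine gene Cxcl2 from 35.0 to 14.5 TPM and the costimulatory gene Cd86 from 36.8 to 23.4 TPM. The monocyte chemokine gene Ccl7, on the same list, rose from 113 to 501 TPM. Nos2, the inducible nitric oxide synthase, was at 1.50 and 0.699 TPM (adjusted p = 0.386), and Il1b at 1.35 and 0.478 TPM (adjusted p = 0.104, but 0.0418 by limma-voom on the recovered reads). Il6 had 0 to 6 reads in each library and was below the filter. Interferon response genes also fell: 16 of 47 fell and 0 rose (22 and 1 adjusted over the list alone, 14 and 0 separated), with a median of -0.26 (camera adjusted p = 4.16e-09). Ifi47, an interferon-inducible GTPase gene, fell from 10.5 to 5.84 TPM.

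Of 23 macrophage identity genes, 10 fell and 2 rose (11 and 3 adjusted over the list alone, 10 and 2 separated; camera adjusted p = 9.84e-05). Cd14 fell from 1527 to 962 TPM and Mpeg1, encoding a pore-forming protein of phagocytes, from 794 to 506 TPM. MHC class II presentation and costimulation genes fell in 8 of 15 cases and rose in 2 (8 and 2 adjusted over the list alone, 4 and 2 separated; camera adjusted p = 0.00812, and adjusted p = 0.324 with an estimated correlation). That call was also lost with a filter of 5 TPM (0.116). The invariant chain gene Cd74 rose against that direction, from 722 to 1276 TPM. Lysosome and phagocytosis genes fell in 16 of 46 cases and rose in 3 (19 and 4 adjusted over the list alone, 10 and 3 separated; camera adjusted p = 0.00138, and adjusted p = 0.413 with an estimated correlation). Ctsc, a cathepsin gene, fell from 132 to 96.4 TPM, whereas Ctsl, another, rose from 325 to 425 TPM.

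Cholesterol synthesis genes rose in 9 of 25 cases and fell in 0 (10 and 0 adjusted over the list alone, 9 and 0 separated), with a median of 0.09 (camera adjusted p = 7.49e-04), and Mvd, of the mevalonate pathway, rose from 126 to 155 TPM. LXR targets and sterol efflux genes rose in 4 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone, 4 and 1 separated; camera adjusted p = 0.00774, and adjusted p = 0.188 with an estimated correlation). Arl4c rose from 81.1 to 159 TPM, and the sterol exporter gene Abca1 fell from 142 to 107 TPM. Heat shock genes rose in 7 of 17 cases and fell in 0 (10 and 0 adjusted over the list alone, 6 and 0 separated; camera adjusted p = 2.14e-04, and adjusted p = 0.188 with an estimated correlation), with Fkbp4 at 506 and 627 TPM. OXPHOS and TCA cycle genes rose in 10 of 50 cases and fell in 0 (18 and 0 adjusted over the list alone, 8 and 0 separated; camera adjusted p = 3.06e-07, and adjusted p = 0.194 with an estimated correlation), with Idh2 at 205 and 239 TPM. Ribosomal protein genes rose in 8 of 43 cases and fell in 0 (10 and 0 adjusted over the list alone, 5 and 0 separated; camera adjusted p = 1.59e-06, and adjusted p = 0.375 with an estimated correlation), with a median of 0.07.

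The 13 mitochondrially encoded genes lay lower by a median of -0.20 (camera adjusted p = 0.0410), with 1 fallen and 0 risen (1 and 0 adjusted over the list alone, 1 and 0 separated). That call was lost with an estimated correlation (adjusted p = 0.413 with an estimated correlation), with quantile normalization (0.473), and without control replicate 1 (0.0719), control replicate 3 (0.0850) or M2 replicate 3 (0.0852). Their share of TPM was 6.83%, 6.55% and 6.69% in the control libraries and 6.15%, 6.58% and 5.44% in the M2 libraries. PPAR targets and fatty acid genes (2 of 32 rose and 4 fell, and 5 and 4 adjusted over the list alone, 0 and 4 separated; camera adjusted p = 0.255), CYP, AhR and xenobiotic genes (0 of 20 rose and 2 fell, and 0 and 1 adjusted over the list alone, 0 and 1 separated; 0.140), NRF2 antioxidant genes (2 of 33 rose and 9 fell, and 4 and 12 adjusted over the list alone, 2 and 6 separated; 0.0703) and glycolysis and hypoxia genes (4 of 35 rose and 1 fell, and 5 and 1 adjusted over the list alone, 3 and 1 separated; 0.0627) did not pass as lists. The NRF2 list passed with quantile normalization (0.00284), without control replicate 1 (0.0442) and without M2 replicate 3 (0.0157), the glycolysis list without control replicate 3 (0.00145) and without M2 replicate 2 (6.65e-04), and the CYP list without M2 replicate 3 (0.0412).

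In all, 977 of 14207 genes rose and 817 fell (limma, adjusted p under 0.05), of which 49 and 36 changed by at least 1 on the log2 scale. The groups did not overlap in 4032 genes (28.4%), where chance gives 10%. For each gene given above as risen or fallen, all 3 M2 libraries lay on one side of all 3 control libraries. With the shared reads separated 1293 genes passed, and all 1293 were among those 1794, and the same 12 lists passed. The count was 1139 without control replicate 1 and 1161 without control replicate 3. Fold changes in this comparison use no Q11 library, but the spread is estimated from all libraries. Libraries that share reads lower that spread, so the p-values, intervals and counts as deposited depend on them. For genes with a mean of at least 5 TPM, the median half-width of the interval was 0.135 as deposited and 0.148 separated. Of the 12 lists that passed, 4 held with an estimated correlation: inflammatory genes (adjusted p = 0.00328), interferon response (0.00328), cholesterol synthesis (0.0391) and macrophage identity (0.0277). Of the 10 largest falls, 4 were small RNA genes with few reads.

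**Figure D2:**
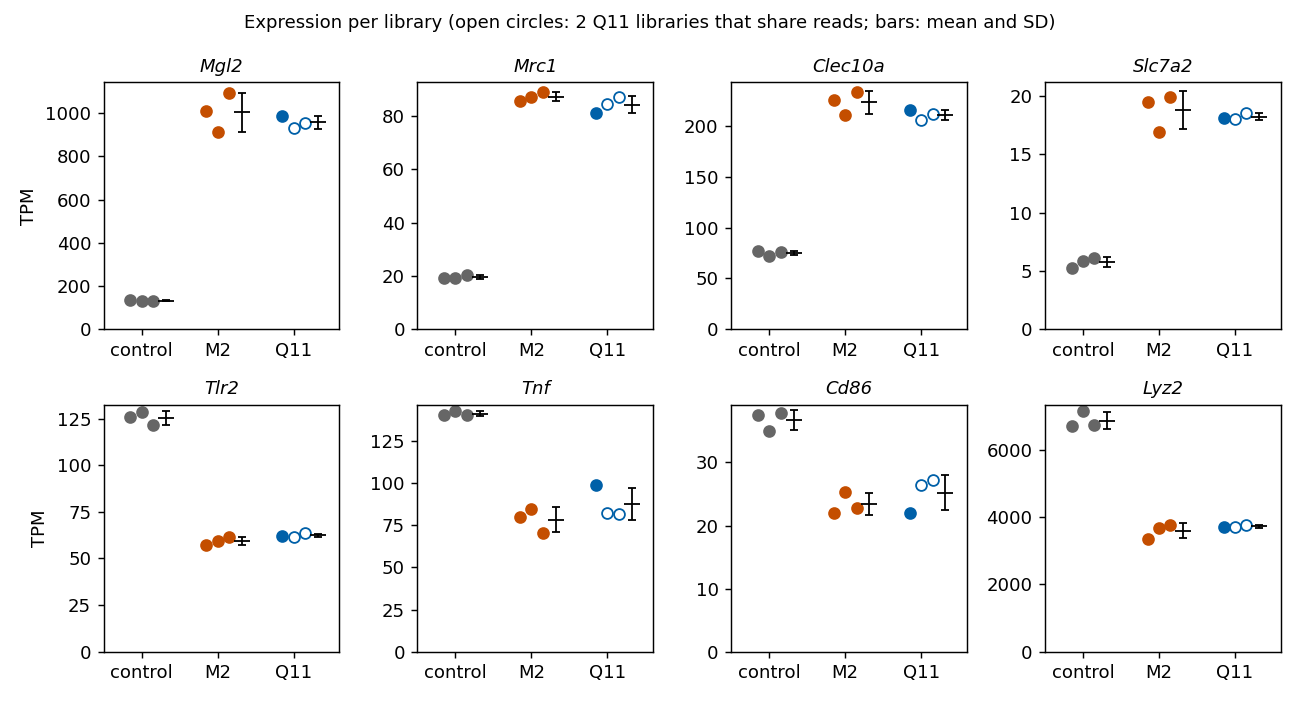
TPM per library of 4 genes that rose and 4 that fell in M2 against control, with each group's mean and SD beside its 3 points and open circles for the Q11 libraries that share reads. For Mrc1, the 3 M2 libraries lay between 85.8 and 89.1 TPM and the 3 Q11 libraries between 81.1 and 87.3 TPM, all above the control libraries.

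Q11 against M2 asked what adding Q11 during the induction changed. Neither the M2 markers nor the inflammatory genes passed as a list. Mrc1 was at 87.3 ± 1.71 TPM without Q11 and 84.3 ± 3.12 TPM with it (SD, n = 3), and Mgl2 at 1004 ± 90.002 and 957 ± 28.7 TPM. Tnf was at 78.3 ± 7.39 and 87.6 ± 9.71 TPM. By limma 0 of 14207 genes passed, and the smallest adjusted p was 0.213.

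The difference in Mrc1 was -0.05 on the log2 scale (95% interval -0.14 to 0.04, adjusted p = 0.645), and with the shared reads separated it was -0.06 (-0.16 to 0.03). Mgl2 differed by -0.07 (-0.19 to 0.06), Clec10a by -0.08 (-0.18 to 0.01) and Slc7a2 by -0.04 (-0.21 to 0.13). Arg1 was lower by more, at 3.56 ± 2.36 and 2.17 ± 1.05 TPM, but its interval was wide (-0.46, from -1.34 to 0.42, adjusted p = 0.675). Its M2 libraries were at 2.86, 1.63 and 6.20 TPM and its Q11 libraries at 1.02, 3.07 and 2.43 TPM. Only M2 replicate 3 lay above all Q11 libraries. For Tnf the difference was 0.16 (-0.03 to 0.35, adjusted p = 0.503), and for Cd86 it was 0.10 (-0.09 to 0.29, adjusted p = 0.665). Il10 was at 7.14 and 5.54 TPM, Tgfb1 at 247 and 232 TPM, Stat6 at 155 and 148 TPM, Il4ra at 16.7 and 16.8 TPM and Pparg at 1.11 and 0.999 TPM. Nos2 was at 0.699 and 0.554 TPM and Il1b at 0.478 and 1.11 TPM. Il1b had 1, 6 and 6 reads in the M2 libraries and 8, 18 and 14 in the Q11 libraries. Its groups did not overlap as deposited, as in 17.6% of all genes, and it did not pass. If reads are shared, the 18 reads of Q11 replicate 2 include the 14 of replicate 3. Chil3 had 6, 9 and 8 reads in Q11 replicates 1, 2 and 3. If reads are shared, the 9 of replicate 2 include the 8 of replicate 3 and are not separate evidence.

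Of the 24 lists, 5 passed by camera with the preset correlation, each by a small median. Mitochondrially encoded genes lay higher by 0.23 (adjusted p = 2.99e-05, and adjusted p = 0.577 with an estimated correlation). Ribosomal protein genes lay lower by a median of -0.06 (6.40e-08), ATF4 amino acid stress genes by -0.05 (7.50e-04) and OXPHOS and TCA cycle genes by -0.04 (0.00136), and each had an adjusted p = 0.577 with an estimated correlation. Glycolysis and hypoxia genes lay lower by -0.04 (0.00444, and adjusted p = 0.672 with an estimated correlation). Over all genes 0 members of any list passed. Adjusted over the list alone, 6 mitochondrially encoded genes and 1 cholesterol synthesis gene lay higher, and 3 ribosomal protein genes, 1 OXPHOS gene and 1 MHC class II gene lay lower. The OXPHOS call was lost with quantile normalization (0.0944), without M2 replicate 3 (0.272) and without Q11 replicate 2 (0.0646), and the glycolysis call without M2 replicate 3 (0.498). Without M2 replicate 3 only 3 lists passed, without M2 replicate 1 or M2 replicate 2 there were 7, and camera with an estimated correlation called 0. Tested against no change by fry, 0 lists passed. The mitochondrially encoded share of TPM was 6.69%, 7.02% and 7.06% in the Q11 libraries and 6.15%, 6.58% and 5.44% in the M2 libraries. The M2 marker list (median -0.07, adjusted p = 0.267), the inflammatory list (0.05, 0.481), the interferon list (-0.02, 0.481), MHC class II genes (-0.06, 0.0659) and CYP, AhR and xenobiotic genes (0.02, 0.852) did not pass.

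At an unadjusted p under 0.05 there were 1620 genes in the fit as deposited and 1133 with the shared reads separated, which also called 0 genes (smallest adjusted p 0.342). By chance a share of 0.05 of the genes tested would pass. Leaving out 1 library gave 865 (without Q11 replicate 3) to 2149 (without M2 replicate 2). With the shared reads separated and M2 replicate 3 left out there were 796. By limma-voom on the recovered reads 2 genes passed as deposited, the ribosomal protein gene Rpl41 (-0.24, adjusted p = 0.00994) and mt-Co1 (0.14, adjusted p = 0.0341), and 0 once the shared reads were separated. Without control replicate 3 the count was 1 (the gene 5S_rRNA), and without M2 replicate 1 it was 2 (Gm16161 and Mir365-2). With no filter on low values it was 3 (1700001D01Rik, Gm25558 and Gm48806), and with no mean-variance trend it was 2 (1700001D01Rik and Gm25558). These genes are named only because so few passed, and were chosen after their values were seen. Groups did not overlap in 17.6% of genes as deposited and in 12.6% with the shared reads separated, where chance gives 10% for independent libraries. Of the 10102 genes with a mean of at least 5 TPM, 97.5% had a 95% interval that lay within 1 on the log2 scale either way, and 97.6% of 10044 did so with the shared reads separated.

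Q11 against control asked what differed from unstimulated cells when Q11 was present. Mgl2 and Mrc1 were again among the 10 largest rises, and inflammatory genes fell as a list. Mgl2 rose 7.26-fold, from 132 ± 1.93 to 957 ± 28.7 TPM (SD, n = 3), and Mrc1 4.30-fold, from 19.6 ± 0.666 to 84.3 ± 3.12 TPM. Tlr2 fell from 125 ± 3.54 to 62.4 ± 0.919 TPM and Lyz2 from 6859 ± 244 to 3722 ± 38.5 TPM. These 4 genes passed with the shared reads separated too.

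Of the 24 M2 markers, 8 rose and 3 fell (12 and 6 adjusted over the list alone, 8 and 3 separated), with a median of 0.37 (camera adjusted p = 0.00121, and adjusted p = 0.168 with an estimated correlation). Mgl2 rose by 2.85 (2.72 to 2.98, limma adjusted p = 1.71e-08) and Mrc1 by 2.05 (1.96 to 2.14, adjusted p = 1.69e-08). Clec10a rose from 75.0 to 211 TPM and Slc7a2 from 5.73 to 18.2 TPM. Arg1 was at 0.302 ± 0.186 and 2.17 ± 1.05 TPM, on 11, 65 and 27 reads in Q11 replicates 1, 2 and 3. If reads are shared, the 65 of replicate 2 include the 27 of replicate 3. The Arg1 difference of 1.23 (0.36 to 2.11) did not pass (adjusted p = 0.0815). It passed with a pseudocount of 0.1 (0.0371), without M2 replicate 3 (0.0405) and by limma-voom (0.0110). In the IL-4 and STAT6 pathway 2 of 19 genes rose and 4 fell (2 and 5 adjusted over the list alone, 2 and 2 separated; camera adjusted p = 0.226; median -0.06, mean 0.02), and Socs1 rose from 1.53 to 6.22 TPM.

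Inflammatory genes fell in 20 of 33 cases and rose in 3 (22 and 3 adjusted over the list alone, 17 and 3 separated; median -0.32, camera adjusted p = 2.33e-11). Tnf fell from 141 ± 1.52 to 87.6 ± 9.71 TPM (adjusted p = 0.00110) and Cd86 from 36.8 to 25.2 TPM, while Ccl7 rose from 113 to 601 TPM. Interferon response genes fell in 20 of 47 cases and rose in 0 (22 and 0 adjusted over the list alone, 14 and 0 separated; median -0.25, camera adjusted p = 4.28e-11), with Ifi27l2a at 69.4 and 46.4 TPM. Macrophage identity genes fell in 9 of 23 cases and rose in 2 (11 and 3 adjusted over the list alone, 9 and 2 separated; camera adjusted p = 9.99e-06), with Cd14 at 1527 and 991 TPM. Cholesterol synthesis genes rose in 10 of 25 cases and fell in 0 (12 and 0 adjusted over the list alone, 8 and 0 separated; camera adjusted p = 1.62e-06), with Mvd at 126 and 154 TPM. These 4 lists were the ones that held with an estimated correlation (adjusted p = 0.00213 for inflammatory and interferon genes, 0.0112 for macrophage identity and 0.00930 for cholesterol synthesis).

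Further lists passed with the preset correlation alone. MHC class II genes fell in 8 of 15 cases and rose in 2 (9 and 2 adjusted over the list alone, 5 and 2 separated; camera adjusted p = 1.41e-04, and adjusted p = 0.173 with an estimated correlation). Lysosome and phagocytosis genes fell in 16 of 46 cases and rose in 3 (21 and 6 adjusted over the list alone, 14 and 3 separated; camera adjusted p = 9.99e-06, and adjusted p = 0.310 with an estimated correlation). NRF2 antioxidant genes fell in 8 of 33 cases and rose in 1 (10 and 1 adjusted over the list alone, 7 and 1 separated; camera adjusted p = 0.00397, and adjusted p = 0.212 with an estimated correlation), with the peroxiredoxin gene Prdx1 at 965 and 780.0 TPM. Heat shock genes rose in 7 of 17 cases and fell in 0 (10 and 0 adjusted over the list alone, 4 and 0 separated; camera adjusted p = 1.31e-05, and adjusted p = 0.131 with an estimated correlation). OXPHOS and TCA cycle genes rose in 10 of 50 cases and fell in 1 (12 and 1 adjusted over the list alone, 5 and 1 separated; camera adjusted p = 0.00186, and adjusted p = 0.426 with an estimated correlation). Ribosomal protein genes (camera adjusted p = 0.289, but 0.00973 without Q11 replicate 2), mitochondrially encoded genes (0.336), LXR targets (0.226), PPAR targets (0.475), CYP, AhR and xenobiotic genes (0.196) and glycolysis and hypoxia genes (0.970) did not pass.

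In all, 738 genes rose and 786 fell (limma, adjusted p under 0.05), 50 and 21 of them by at least 1 on the log2 scale. With the shared reads separated 555 rose and 545 fell, which turned the balance, and 1097 of these 1100 genes were among those 1524. The same 11 lists passed then, 4 of them with an estimated correlation. Without Q11 replicate 2 the count was 798 and without Q11 replicate 3 it was 776. The groups did not overlap in 4562 genes (32.1%) as deposited and in 3737 of 13971 (26.7%) with the shared reads separated, where chance gives 10% for independent libraries. Of the 10 largest rises, 3 were small RNA genes (Mir7048, Mir128-1 and Snord93), and 1 of the 10 largest falls was (Mir142b). With the shared reads separated Mir7048 (adjusted p = 0.309) and Mir128-1 (0.203) did not pass, and Snord93 was not tested. For each other gene given above as risen or fallen, all 3 Q11 libraries lay on one side of all 3 control libraries, and the gene also passed with the shared reads separated.

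The changes from control without and with Q11 were then set side by side. Of the 1794 genes called in M2 against control, 1774 (98.9%) had the same sign in Q11 against control, and the slope of the second change on the first was 0.782. With the shared reads separated this was 1288 of 1293 genes (99.6%), with a slope of 0.834. Neither slope was cross-fitted. The genes were chosen, and the first change measured, on the same M2 libraries, which draws the slope down. It is therefore not the share of the change kept with Q11, and the cross-fitted slope is given below. Both changes share their controls and the genes were chosen on the first, so unchanged groups also give high values: in 100 simulations the same number of genes had the same sign in 84.9% (82.6% to 87.0%) with a slope of 0.503 (0.440 to 0.576), and in 86.4% (84.0% to 88.9%) with a slope of 0.4995 (0.428 to 0.598) with the shared reads separated. Over all genes 74.8% had the same sign, beside 66.7% (65.9% to 68.0%) in the simulations. Genes called in both comparisons numbered 548 up in both and 551 down in both, against 50.8 and 45.2 for independent lists, and 0 were called in opposite directions. Across 14207 genes, which are not independent replicates, the changes correlated with Pearson's r of 0.583, and the covariance was 0.0583. In 100 simulations of unchanged groups against the same controls the mean correlation was 0.4998 (0.448 to 0.544), the mean covariance 0.0258 and the mean number of genes called in both 0.03. With 3 control libraries no split keeps 2 on each side, and part of the excess over independent lists may come from the shared controls.

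**Figure D3:**
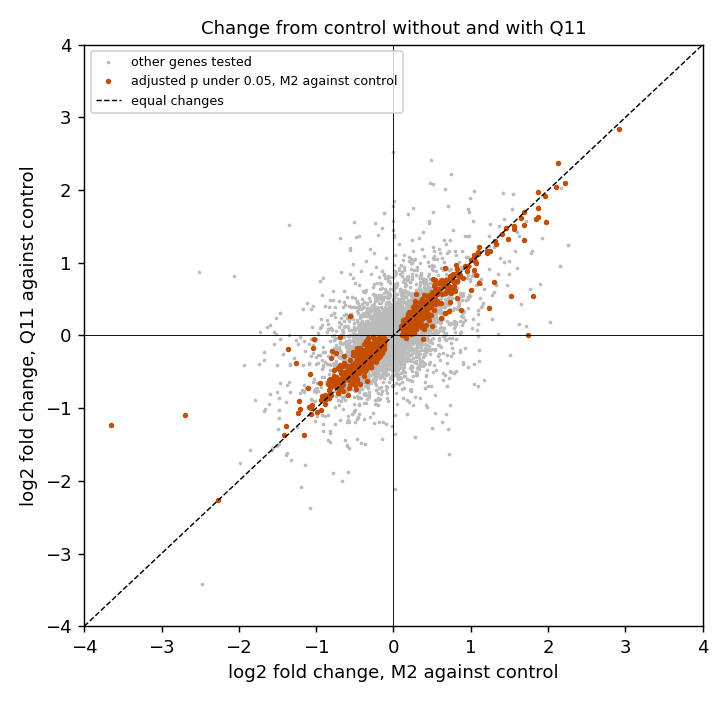
Log2 fold change of each gene tested in Q11 against control (vertical axis) over that in M2 against control (horizontal axis), with the shared reads separated. Values are on the log2(TPM + 1) scale, and a dashed line marks equal changes. Genes at an adjusted p under 0.05 in M2 against control in that fit are orange. Of the 1293 orange points, 1288 (99.6%) had the same sign on both axes, beside 86.4% in simulations of unchanged groups that share the controls.

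Cross-fitted over the M2 libraries, the slope of the Q11 against M2 change on the M2 against control change was -0.0280 over genes called in M2 against control (SD 0.0395 over 6 splits, from -0.0881 to 0.0266). A slope of 0 means levels as in the M2 libraries, and -1 means levels back at control. With the shared reads separated the slope was -0.00806 (-0.0535 to 0.0220). Other settings of the cross-fitted slope gave -0.0668 (a filter of 5 TPM) to -0.00123 (without control replicate 3). Across all genes these changes correlated with r of -0.449 and a covariance of -0.0408. In the simulations, in which both comparisons use the same M2 libraries, r was -0.502 (-0.539 to -0.450) and the covariance -0.0260 (-0.0297 to -0.0221). The observed covariance thus lay below the simulated range and the correlation just above its range, so these measures differ in direction. The simulated groups held no M2 against control change, unlike these data, and each gene had the same spread in every group. Neither measure can therefore decide whether Q11 moved levels towards control.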

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

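The alternatives that use the shared reads, averaging of the Q11 libraries or limma-voom were added after the result was seen, and the others were fixed before the data were examined. No list that passed changed direction under another scaling, while some lists that did not pass did. Unless a reason is given, the cause was not tested.

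In M2 against control 1794 genes passed. A fit of these groups alone gave 1054, a further threshold of 1 on the log2 fold change gave 85, and separation of the shared reads with M2 replicate 3 left out gave 843. Leaving out 1 library at a time gave 1139 to 1651, the lowest without control replicate 1, followed by 1161 without control replicate 3. Of the 12 lists that passed, 4 were left when the correlation between genes was estimated.

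In Q11 against M2 0 genes passed. The count was 3 with no filter on low values, 2 with eBayes without trend, 2 by limma-voom on recovered reads and 0 by limma-voom with the shared reads separated. Leaving out 1 library at a time gave 0 to 2, with 2 without M2 replicate 1. Of the lists, 5 passed, against 0 by camera with an estimated correlation, 0 by fry, 2 with the shared reads separated and M2 replicate 3 left out, and 3 to 7 with 1 library left out, the lowest without M2 replicate 3.

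In Q11 against control 1524 genes passed. A further threshold of 1 on the log2 fold change gave 71, and the average of Q11 replicates 2 and 3 as 1 library gave 795. Leaving out 1 library at a time gave 776 to 1613, the lowest without Q11 replicate 3. Of the 11 lists that passed, 4 were left with an estimated correlation.

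Fry tests a list against no change and camera against all other genes, so they ask different questions. By fry 16 lists passed in M2 against control and 14 in Q11 against control. Only fry called cell death, ER unfolded protein and housekeeping genes in both, NRF2 and matrix genes in the first and LXR targets in the second. Only camera called mitochondrially encoded genes in the first (fry adjusted p = 0.0926) and OXPHOS genes in the second (0.0594).

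The slope of Q11 against M2 on M2 against control was -0.218 when not cross-fitted and -0.0280 when cross-fitted. By construction the first uses the same M2 libraries on both sides, which gives a negative slope without any change. Cross-fitted, the slope was -0.0668 with a filter of 5 TPM, -0.0618 as a median ratio, -0.0598 with a pseudocount of 0.1, and -0.0515 (without Q11 replicate 3) to -0.00123 (without control replicate 3) with 1 library left out.

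Replicate numbers are shared by the groups in the labels. With a replicate block the counts were 1335, 0 and 1086 genes in the order above, with 13, 5 and 11 lists and a slope of -0.0248, and among the lists only glycolysis and hypoxia genes in M2 against control were added (adjusted p = 0.0319), and 25 of 198 calls of genes chosen by the naming rule were lost. Deviations from the group mean correlated at -0.0309 to 0.0362 between libraries of the same number, so the libraries share a number and no visible batch.

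In M2 against control 54.5% of calls were rises, with 51.4% under quantile normalization and 50.7% with 34 mitochondrial and dominant genes removed. The balance turned in other fits, to 651 rises and 661 falls with eBayes without trend, 1122 and 1135 by limma-voom, 941 and 972 by limma-voom with the shared reads separated, and 404 and 439 with the shared reads separated and M2 replicate 3 left out. In Q11 against control the balance turned, from 738 rises and 786 falls (48.4% rises) to 793 and 764 (50.9%) with those genes removed and to 555 and 545 with the shared reads separated (564 and 544 with M2 replicate 3 left out as well), and it was 45.0% rises under quantile normalization. Quantile normalization added NRF2 genes in M2 against control (adjusted p = 0.00284) and cholesterol synthesis genes in Q11 against M2 (0.0300), and it lost mitochondrially encoded genes in the first (0.473) and OXPHOS genes in the second (0.0944).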

Other observations

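Matrix and angiogenic genes of tumour-associated macrophages moved in both directions with IL-4 and IL-13. Of 29, 6 rose and 12 fell in M2 against control (9 and 12 adjusted over the list alone, 6 and 10 separated; camera adjusted p = 0.140, but 0.0429 with a filter of 5 TPM), and 6 rose and 10 fell in Q11 against control (8 and 13 adjusted over the list alone, 5 and 9 separated; 0.0243, and adjusted p = 0.131 with an estimated correlation). Osteopontin, from Spp1, fell from 6844 to 4112 TPM and was at 4258 TPM with Q11, while the collagenase gene Mmp13 rose from 23.1 to 37.1 TPM and was at 38.0 TPM with Q11. On the cell death and ferroptosis list, the transferrin receptor gene Tfrc rose from 648 to 945 TPM and the iron exporter gene Slc40a1 fell from 6.92 to 4.40 TPM, with 996 and 4.12 TPM in the Q11 libraries. That list did not pass (3 of 28 rose and 7 fell in M2 against control, and 4 and 7 adjusted over the list alone, 2 and 6 separated; adjusted p = 0.152; in Q11 against control 0.226). Of 22 p53 targets, 4 rose and 3 fell in M2 against control (6 and 5 adjusted over the list alone, 3 and 3 separated; median 0.05, mean -0.03, camera upward), and 5 rose and 2 fell in Q11 against control (7 and 2 adjusted over the list alone, 2 and 2 separated; median 0.01, mean -0.01, camera upward). The list did not pass in either (0.542 and 0.455), and in M2 against control Pmaip1 fell from 82.9 to 46.6 TPM and Aen rose from 31.4 to 39.0 TPM.

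Cell cycle genes did not pass as a list in M2 against control (3 of 57 rose and 1 fell, and 1 and 1 adjusted over the list alone, 2 and 0 separated; adjusted p = 0.5002) or Q11 against control (0.455), and Cdc20 rose from 227 to 280.2 TPM in M2 against control. ER unfolded protein genes (0.391; 0.244 in Q11 against control), ATF4 amino acid stress genes (0.101; 0.542) and housekeeping genes (0.374; 0.451) did not pass, although the ATF4 list passed without M2 replicate 2 (0.0384). Pdia4, an ER chaperone gene, rose from 415 to 554 TPM and was at 554 TPM with Q11. In Q11 against M2 the STAT6 pathway (adjusted p = 0.528), PPAR targets (0.528), p53 targets (0.528), cell death (0.668), NRF2 (0.481), cholesterol synthesis (0.145), LXR targets (0.0869), lysosome (0.113), matrix (0.313), ER (0.978), macrophage identity (0.978), heat shock (0.738), cell cycle (0.984) and housekeeping lists (0.990) did not pass. Cholesterol synthesis genes passed with quantile normalization (0.0300), LXR targets without M2 replicate 2 (0.0188), lysosome genes without M2 replicate 1 (0.0111) or M2 replicate 2 (0.0145), and MHC class II genes without M2 replicate 1 (0.00633). Markers of other cell types were low in all groups, with summed means of 3.48, 2.66 and 2.11 TPM for fibroblast genes in control, M2 and Q11 libraries. Epithelial and hepatic genes summed to 25.0, 26.1 and 24.3 TPM, lymphoid genes to 12.3, 11.7 and 10.6 TPM, granulocyte and dendritic cell genes to 36.1, 28.6 and 22.6 TPM, and endothelial and erythroid genes to 5.77, 5.64 and 5.32 TPM. S100a8, a granulocyte gene, was at 32.2 TPM in control and 17.4 TPM in Q11 libraries (-0.84, adjusted p = 0.0180, with all 3 Q11 libraries below all 3 controls), a call lost without control replicate 1 (0.0610), Q11 replicate 1 (0.0547) or Q11 replicate 2 (0.0681).

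The tests of shared reads, of the mitochondrial share of TPM and of power were chosen after the result was seen, and the test of random groupings before it. Those of M2 replicate 3 and of gene length were written down before their own outcome was seen. They ask about a pattern found in these results, however, and use the fit with the shared reads separated, which was chosen after seeing the data.

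Q11 replicate 2 had fewer reads than Q11 replicate 3 in only 10 genes. In 100 Poisson draws of independent libraries at these depths the lowest such number was 1221, so a deeper but separate library does not account for it. The count of 10 is consistent with the reads of Q11 replicate 3 being counted again in Q11 replicate 2. Without those reads, what was left differed from Q11 replicate 3 by a chi-square per gene of 4.57, within the range of 2.34 to 5.11 for other pairs of replicates. The upper end of that range was M2 replicates 2 and 3, and the lower end Q11 replicates 1 and 3. From Q11 replicate 1 the remainder differed by 4.59. It was thus less like the other Q11 libraries than they were like each other. The deposited table does not tell what was merged or when.

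In Q11 against M2, mitochondrially encoded genes lay higher and ribosomal protein genes lower as lists, although neither call held with an estimated correlation (adjusted p = 0.577 for each). With the shared reads separated, both lists still passed by camera with the preset correlation without M2 replicate 3 (larger adjusted p 3.10e-05). The medians moved from 0.22 and -0.07 to 0.15 and -0.04, and only 2 lists still passed. Once a trend with gene length was removed, the larger adjusted p was 6.01e-05, and the medians were 0.21 and -0.08. The directions were kept in both tests. The preset correlation was 0.01, however, where 0.29 and 0.38 were estimated for these lists, so these p-values cannot exclude either explanation. The shift might come from Q11, but the exact permutation p of the mitochondrially encoded share of TPM was 0.1, the smallest possible with 3 libraries against 3. Differences in culture or RNA handling between the groups were not tested.

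No gene passed in Q11 against M2. Among genes with a mean of at least 5 TPM, low power for 2-fold changes does not account for that, since 97.6% of them had an interval within such a change. Tested genes below that level were not covered by this check. Smaller changes could have been missed, and only 51% of simulated changes of 0.5 were recovered. That simulation set its spread and drew Q11 replicate 2 as an independent library at its full depth. The 51% is therefore not the power of this comparison.

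Regrouping gives too few splits for a share under 0.05, since each comparison has 10 splits. In M2 against control 1 of 10 had as many genes as the real grouping (1794, and at most 3 in another), and in Q11 against control 1 of 10 (1524, and at most 4). In Q11 against M2 all 10 of 10 had at least the 0 genes of the real grouping. No split could have fewer, so this outcome tells nothing about the grouping. The most was 5, in the split that set M2 replicate 1 with Q11 replicates 2 and 3.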
